A study of Pinus pinaster with 24 samples.

How the data were processed

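RNA was measured in root tips of maritime pine (Pinus pinaster) seedlings of 1 month. Per the labels' protocols, seedlings were acclimated for 3 days without a nitrogen source. They were then irrigated with 80 mL of 3 mM potassium chloride (KCl, the control) or 3 mM potassium nitrate, and roots were collected 2 h later. Sections of 30 µm were cut from frozen root tips, and 4 areas were isolated by laser microdissection by their position: root cap, root meristem, developing cortex and developing vascular tissue. Per the labels, the protocol kept RNA with an integrity number above 7, amplified cDNA with a kit for low RNA input and sequenced it as paired-end reads of 150 bp. Each of the 8 combinations of area and solution has 3 libraries numbered by experiment, which makes 24 libraries.

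Per the submitters' processing notes, bcl2fastq and BWA were used, with no version named. The read counter, the reference transcriptome, its annotation and the scaling method are not given in the sources used here. The deposited table holds 51211 transcripts, and its values are a scaled count signal that the authors named CPM. Columns of plain CPM share a common total, but the column totals here ran from 786966 to 1173830 CPM, so a scaling factor beyond the library total had been applied. In every column, 100% of the values were whole multiples of the value of a single read within a tolerance of 0.02 reads. The reads recovered in this way summed to 45262154 to 51517525 per library. A single read was worth 0.0171 to 0.02468 CPM. All transcripts reached 1 CPM in at least 2 libraries, which is a property of the deposited table.

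The tests had been planned for plain CPM and were kept for this signal, since both need a test on a log scale. Values were tested as log2(CPM + 0.5) with limma 3.58.1 in R 4.3.3, with a trend of the variance on the mean and the Benjamini-Hochberg adjustment within each contrast. Transcripts with at least 1 CPM in at least 3 libraries were tested, which kept 51044 and left out 167. All 24 libraries entered a model of 8 group means that shares 1 estimate of the spread per transcript. A call means an adjusted p below 0.05. Fold changes are on the log2(CPM + 0.5) scale, which understates changes of transcripts with low values. Contrasts were nitrate minus KCl in each area, their mean over the 4 areas, an F test of the differences between the 4 nitrate effects, and each area against the mean of the other areas. A transcript was called highest in an area when it was higher there than in each other area. The count test of edgeR 4.0.16 (quasi-likelihood) was run on the recovered reads, and DESeq2 1.42.0 was an alternative added later.

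The experiment numbers were checked for pairing before the fits were compared. Deviations from the group means correlated between areas with the same solution and number in all 36 pairs, at 0.279 to 0.694 across transcripts. All 24 libraries matched their own number best in each other area of the same solution. The libraries with the same solution and number are therefore treated as 1 root-tip set, which makes 6 sets. The pairing comes from these values and is not stated in the labels, and shared plants, a shared day or a shared processing batch would all give it. Libraries of 1 set are not independent, so p-values over areas are too small for the mean nitrate effect, and values from the set means are given beside it. The labels do not say how many seedlings made up a set or whether the experiments were separate cultures, so p-values measure the spread between these libraries only.

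The procedure was tested on simulated counts drawn from the KCl means of the 51044 transcripts, with 200 transcripts changed in 1 area at a time. The changed transcripts had a KCl mean of at least 1 CPM in that area, so the recovery does not cover lower levels. The shares of false calls also depend on this number of changes. The main limma test recovered 66% to 77% of changes of 2 on the log2 scale and 16% to 22% of changes of 1. Its share of false calls was 56.7% for the root cap, 12.8% for the meristem, 23.9% for the cortex and 44.6% for the vascular tissue. The edgeR test recovered 57% to 65% and 12% to 15% of these changes, with 2.5% to 9.52% false calls. The counts were drawn with 1 dispersion per transcript for all areas, which is the model that edgeR fits, so its share of false calls may be higher in the real libraries. The main test had been fixed before the data were examined and was kept, and edgeR counts are given beside its counts.

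The sources used here do not pair the transcript IDs with gene names: 0 of the 51211 IDs had a name. The gene lists chosen before the data were examined, on nitrogen nutrition, hormones and tissue markers, could therefore not be tested, and no list result is given. By a rule fixed before the data were examined, at most 2 higher and 2 lower IDs per contrast are named. They are the smallest p-values among transcripts with an absolute log2 fold change of at least 1 and no overlap between the libraries compared. For the mean nitrate effect the rule asked for the same sign in all areas. IDs with adjacent numbers may be near-identical copies between which reads were split, so their separate values are uncertain. Folds against groups with 0 reads are lower bounds against 3 reads per library, and such floors cover counting error only, since amplified reads are not independent molecules.

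Alternatives were pseudocounts of 0.1 and 2, no filter, a filter at 5 CPM, quantile and median-of-ratios scaling, library weights, no variance trend, the replicate block, fits on the libraries of an area alone, KCl libraries alone, edgeR, and leaving out each library. Further alternatives were chosen after seeing the data: voom, DESeq2, a random effect of the root-tip set, set means, edgeR on reads summed per set, edgeR with a block, an area filter, and leaving out whole sets.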

Results

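Gene expression was measured in 24 libraries from 4 laser-microdissected areas of the maritime pine root tip, 2 h after irrigation with 3 mM KCl or 3 mM potassium nitrate. The areas were the root cap, the root meristem, the developing cortex and the developing vascular tissue, with 3 libraries per area and solution. The recovered reads amounted to 45262154 to 51517525 per library, and between 1.757% and 5.163% of the 51211 transcripts had no read in a library. With 3 reads as the detection limit, this depth resolves values below 0.1 CPM in every library. The 10 most abundant transcripts held 8.77% ± 0.48 (SD, n = 6) of the CPM in root cap libraries, compared with 3.25% ± 0.37 in the meristem, 2.89% ± 0.13 in the cortex and 3.67% ± 0.41 in the vascular tissue (SD, n = 6 each).

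The areas separated the libraries far more than the solutions did. The first principal component held 61.5% of the variance and parted the root cap from the other areas, and the second held 11.3%. Across transcripts, which are not independent replicates, Pearson's r was 0.902 to 0.967 between libraries of the same area and solution, with a median of 0.948. It was 0.902 to 0.96 between solutions of the same area, with a median of 0.944, and the median between areas was 0.783. The root cap was least similar to the vascular tissue (median r of 0.457), and the meristem was most similar to the cortex (0.864) and the vascular tissue (0.86). No pair of replicate libraries looked like a library deposited again (chi-square of the reads per transcript of 35.32 to 175.4 over the 24 pairs), so each was counted as a separate replicate.

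**Figure D1:**
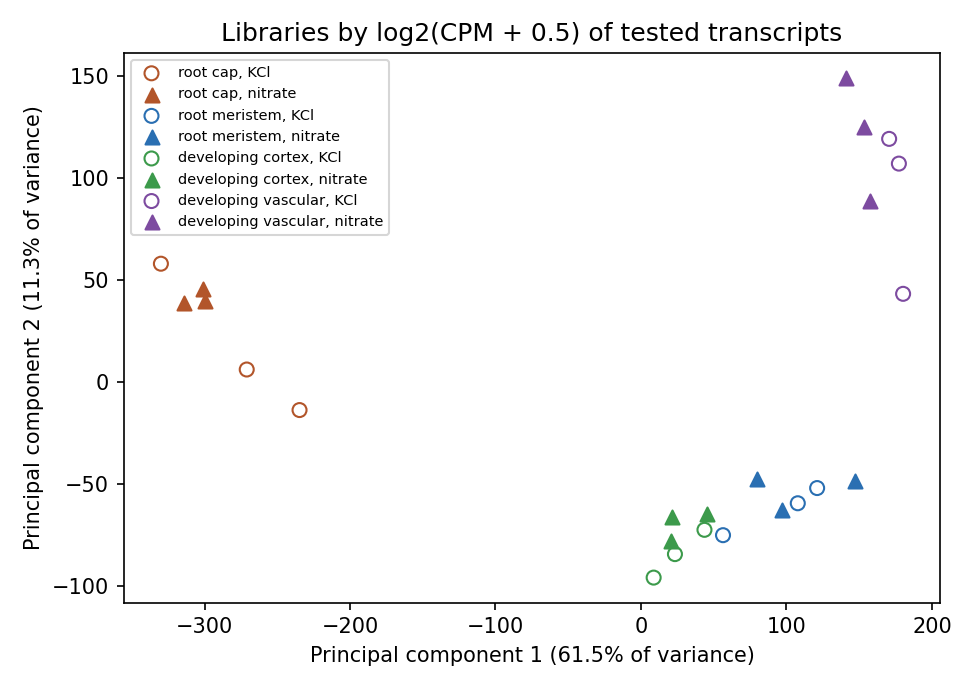
Each point is a library, placed by its scores on principal components 1 (x axis, 61.5% of the variance) and 2 (y axis, 11.3%), in arbitrary units of the log2 values. Colours mark the 4 areas, open circles KCl and filled triangles nitrate; the root cap libraries lie apart on component 1, and the solutions of an area lie close beside the distance from the cap to the other areas, without overlap on component 1 in the vascular tissue (140.9 to 157.6 with nitrate, 170.6 to 180.2 with KCl).

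The comparison of areas asked which transcripts mark each part of the root tip, over the libraries of both solutions. The root cap stood furthest apart. Of the 51044 transcripts tested, 19528 were higher and 20962 lower in the cap than in the mean of the other areas, and 14566 were higher there than in each other area. The slight lead of lower transcripts turned under median-of-ratios scaling (20996 higher and 19408 lower) and by edgeR (20465 and 19478). These cap-highest transcripts held 62.7% ± 4.77 (SD, n = 6) of the CPM in cap libraries and 15.8% ± 3.59 (SD, n = 18) in the others, and 522 of them were at least 16-fold above the next area. The transcript pp_235229 had 2162 ± 766 CPM in the cap (SD, n = 6) and 0.0938 ± 0.201 CPM elsewhere (SD, n = 18), and pp_114011 had 2490 ± 870 CPM and 0.0873 ± 0.237 CPM. In the other direction, pp_178458 had 0.692 ± 0.414 CPM in the cap and 60.4 ± 21.8 CPM elsewhere, and pp_178459 had 0.525 ± 0.386 and 42.01 ± 14.5 CPM. Values elsewhere, here and for the other areas, pool the remaining areas, so their SD also holds differences between those areas.

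The developing vascular tissue had 16270 higher and 15225 lower transcripts, and 2509 were highest there, 99 of them by at least 16-fold. The transcript pp_199413 had 10.4 ± 4.58 CPM in vascular libraries (SD, n = 6) and 0.0353 ± 0.0808 CPM elsewhere (SD, n = 18), while pp_58111 had 23.7 ± 17.3 and 0.137 ± 0.161 CPM. The lower transcript pp_197336 had 0.063 ± 0.05 CPM in vascular libraries and 91.7 ± 109.5 CPM elsewhere, and pp_189385 had 5.58 ± 2.26 and 137.9 ± 85.3 CPM. The 2509 vascular-highest transcripts held 6.12% ± 0.898 (SD, n = 6) of the CPM in vascular libraries and 1.82% ± 0.808 (SD, n = 18) in the others.

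In the developing cortex, 12460 transcripts were higher and 9443 lower, and 1622 were highest there, 24 of them by at least 16-fold. The transcript pp_202775 had 21.5 ± 8.63 CPM in cortex libraries (SD, n = 6) and 0.434 ± 0.244 CPM elsewhere (SD, n = 18), and pp_112453 had 4.47 ± 1.02 and 0.0618 ± 0.0755 CPM. The transcripts pp_152746 and pp_118297 were lower, with 3.65 ± 1.04 against 21.8 ± 5.86 CPM and 2.8 ± 1.23 against 17.6 ± 10.9 CPM. In the KCl libraries alone, 7158 transcripts differed in the cortex, in a test with fewer libraries. The share of higher calls in the cortex was 56.9% here and 66.3% by edgeR, where 13862 transcripts were higher and 7040 lower. Under other scalings the balance was nearly even, with 10869 higher and 10660 lower by median-of-ratios scaling and 11086 and 10981 by quantile normalization.

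The meristem had 16612 higher and 15191 lower transcripts but few that stood far above every other area: 1325 were highest there, and 0 of them by at least 16-fold. The transcript pp_100461 had 22.5 ± 3.62 CPM in the meristem (SD, n = 6) and 8.71 ± 6.17 CPM elsewhere (SD, n = 18), and pp_143803 had 8.55 ± 3.04 and 1.32 ± 2.0 CPM. Neither was low in every other area. Group means of pp_100461 were 0.188 to 0.964 CPM in the cap but 11.55 to 13.85 CPM in the cortex and vascular tissue. Those of pp_143803 were 3.21 and 4.64 CPM in the cap and 0.00671 to 0.0191 CPM in the cortex and vascular tissue. The transcripts pp_209458 and pp_209461 were lower, with 0.0337 ± 0.0414 against 15.8 ± 14.4 CPM and 0.0317 ± 0.0435 against 16.7 ± 14.6 CPM. In the KCl libraries alone, 16700 transcripts differed and 277 were highest in the meristem. With the root-tip set as a block, 2047 transcripts were highest in the meristem. The median-of-ratios scaling turned the majority in this area, with 14887 higher and 16521 lower transcripts. The counts of transcripts that differed in the 4 areas rose with that block, by less than 1.5 times.

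The comparison of solutions asked how each area responded to nitrate within 2 h. The clearest rise was shared by all 4 areas. The transcript pp_103534 rose from 0.118 ± 0.131 to 12.3 ± 4.57 CPM in the cap, from 0.018 ± 0.0311 to 6.06 ± 0.888 in the meristem, from 0.144 ± 0.125 to 9.42 ± 1.04 in the cortex and from 0.0602 ± 0.0551 to 6.77 ± 0.69 in the vascular tissue (SD, n = 3 each). Its neighbour by number, pp_103535, rose from 0.0811 ± 0.0903 to 6.16 ± 2.28 CPM over all areas (SD, n = 12 each). The changes of pp_103534 were 3.66 to 4.34 on the log2 scale with a standard error of 0.226, and the largest of the 4 adjusted p-values from limma was 5.58e-08. With edgeR, the adjusted p-values of pp_103534 in the 4 areas lay between 0.00146 and 0.00407.

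Several transcripts were present with KCl and nearly absent with nitrate. The transcript pp_64764 had 11.4 ± 6.1 CPM in KCl cap libraries and 0 reads in all 12 nitrate libraries, at least 172-fold lower in the cap and at least 127-fold lower in the cortex. It fell in the cap, the meristem and the cortex by limma (adjusted p = 1.11e-07, 0.000759 and 8.75e-07) and by edgeR (0.001, 0.00535 and 0.000805). Groups with 0 reads have no spread, which lowers the spread that limma shares over the groups. The 0.52 ± 0.25 CPM of pp_64764 in KCl vascular libraries gave an adjusted p of 0.196 there by limma and 0.0136 by edgeR. The transcript pp_93274 had 9.82 ± 3.99 CPM in KCl cap libraries and 0 reads in nitrate cap libraries, at least 148-fold lower, and at least 89.8-fold lower in the meristem. Over all 12 nitrate libraries it had 1 read, in the cortex. Its fall in the vascular tissue had an adjusted p of 0.137 by limma and 0.0149 by edgeR. In the vascular tissue, pp_86567 was at least 45.1-fold lower, from 2.54 ± 0.76 CPM. The transcript pp_93557 fell from 10.5 ± 7.22 to 0.0129 ± 0.0223 CPM in the meristem and from 7.79 ± 4.22 to 0.025 ± 0.0433 CPM in the vascular tissue (SD, n = 3 each).

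**Figure D2:**
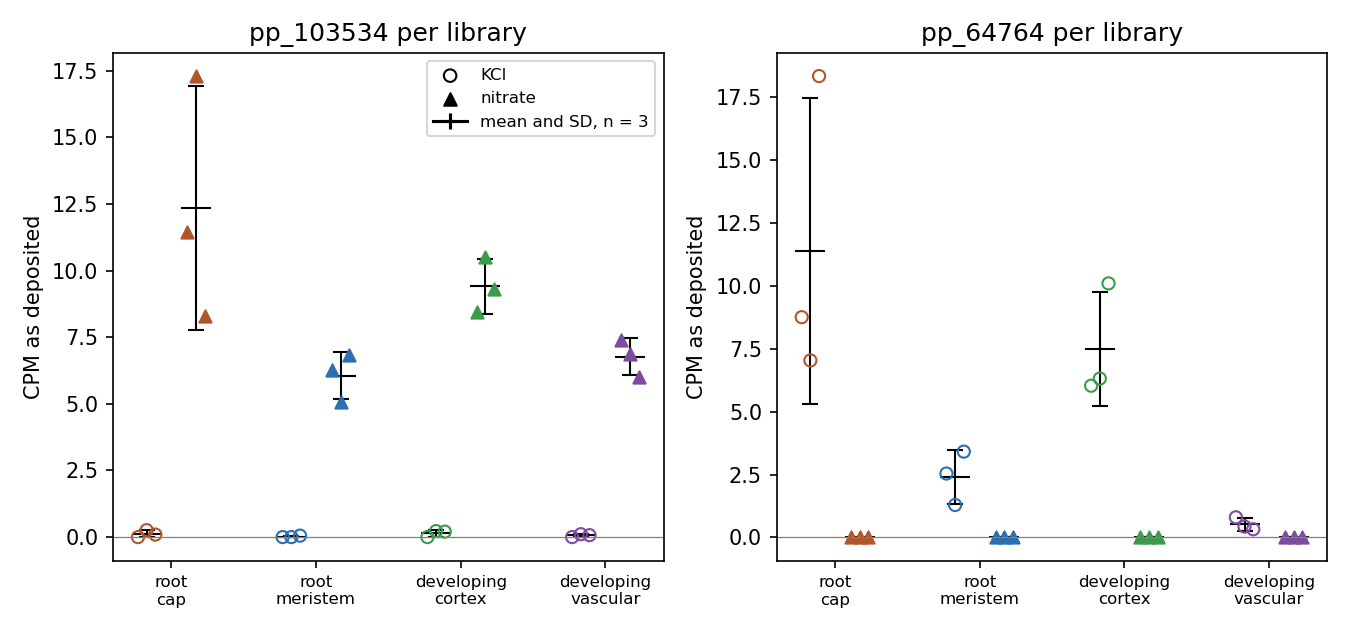
CPM (y axis) of pp_103534, the leading rise, and pp_64764, the leading fall in the root cap, in each of the 24 libraries by area (x axis), with open circles for KCl and filled triangles for nitrate and bars for the mean and SD of 3 libraries. With nitrate pp_103534 reached group means of 6.06 to 12.3 CPM, and pp_64764 had 0 reads.

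In the root cap, limma called 463 transcripts, 354 higher and 109 lower with nitrate. The median change of the higher ones was 1.56 on the log2 scale. This balance depended on the test: edgeR called 38 higher and 80 lower, and both tools shared 31 higher and 45 lower calls. Of the 354 rises, 300 had their highest level in the cap, which is 84.7% against 39.1% of all tested transcripts (Fisher's exact test, odds ratio 8.76, adjusted p = 6.76e-69). Fisher's exact test, here and for the other areas, takes transcripts as independent. They come from the same libraries, and adjacent IDs may be copies, so its p-values do not measure the spread between libraries. The highest level is that of the area means over both solutions. A rise in an area lifts its own mean there, and limma can hardly call a change near the floor. A surplus in the area of the rise is therefore partly built in. Among the 38 rises called by edgeR, 12 had their highest level in the cap (31.6%, odds ratio 0.718, adjusted p = 0.57 by Fisher's exact test). The placing of the falls also depended on the test. Of the 80 called by edgeR, 41 had their highest level in the meristem (51.2% against 25.6% of all, adjusted p = 9.94e-06) and 6 in the cap (7.5%, adjusted p = 8.32e-09), but of the 109 called by limma, 19 had it in the meristem (17.4%, adjusted p = 0.102) and 34 in the cap (31.2%, adjusted p = 0.147). In the cortex it was 32 of the limma falls (29.4% against 12.2%, adjusted p = 9.38e-06) and 11 of the edgeR falls (13.8%, adjusted p = 0.762, Fisher's exact test for each). The limma call of 463 became 2626 without KCl replicate 3 of the cap, with 1041 higher and 1585 lower, and 785 without nitrate replicate 2. In simulated counts, 56.7% of the limma calls for this area were false. The simulation drew libraries independently and did not score the calls shared by both tools, so how firm these are was not tested.

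In the developing vascular tissue, 194 transcripts were higher and 18 lower with nitrate by limma, and 64 and 14 by edgeR, of which 62 and 11 were shared. The rises outnumbered the falls with both tools. The cap-highest transcripts also held more of the CPM in these vascular libraries with nitrate, 14.2% ± 1.7 against 10.6% ± 1.39 with KCl (SD, n = 3 each, two-sided exact permutation p = 0.1, the smallest possible, tested after the data had been seen). Of the 194 limma rises, 100 had their highest level in the vascular tissue (51.5% against 23.1% of all, Fisher's exact test, adjusted p = 6.81e-17), but only 5 of the 64 edgeR rises did (7.81%, adjusted p = 0.0128 for a share below that of all). Of those 64, 38 had their highest level in the cap (59.4% against 39.1%, adjusted p = 0.00807). These values do not tell a response to nitrate from a different mix of tissue between the vascular libraries. In simulated counts, 44.6% of the limma calls for this area were false. The surplus of limma rises with their highest level in the vascular tissue is partly built in, as described for the cap. The limma count was 405 without KCl replicate 3 of this area, 140 without KCl replicate 1 and 106 without nitrate replicate 2.

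In the developing cortex, 82 transcripts were higher and 24 lower by limma, and 39 and 12 by edgeR, of which 38 and 12 were shared. The median change was 2.21 for the higher and -2.49 for the lower ones on the log2 scale. Of the 82 limma rises, 39 had their highest level in the cortex (47.6% against 12.2% of all, adjusted p = 2.21e-14, Fisher's exact test), compared with 10 of 39 edgeR rises (25.6%, adjusted p = 0.0825). As in the cap, a surplus in the area of the rise is partly built in. The meristem had the fewest calls, 19 higher and 21 lower by limma, and 8 and 9 by edgeR, of which 7 and 9 were shared. Tests on the 6 libraries of an area alone called 0 transcripts in the cap and 0 in the meristem by limma. At an unadjusted p below 0.05 they had 2195 and 2392, both fewer than a share of 0.05 of the 51044 transcripts. These tests thus showed no surplus of small p-values. With limma on all libraries, the meristem (2269) was also below this share and the cortex (2553) close to it. The cap (5125) and the vascular tissue (5384) were above it. On all libraries edgeR called 118 in the cap and 17 in the meristem. With a filter of 1 CPM in 3 of its 6 libraries, limma on an area alone called 6 and 1. In simulated counts this filtered test recovered 0% of the changes in the cap and the meristem.

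Across areas, 685 transcripts were called in at least 1 area by limma, and 0 were higher in 1 area and lower in another. In at least 3 areas, 25 transcripts were higher and 17 lower, of which 9 and 3 were called in all 4. Both lists hold adjacent IDs, which may be copies, so these are not counts of independent genes. With edgeR, 12 of the 25 and 7 of the 17 were also called in at least 3 areas. The cortex and the vascular tissue shared 40 rises, where independent lists of the same sizes would share 0.312. Libraries of 1 set deviated together across areas, so part of this overlap may come from differences between the sets and not from nitrate.

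Over the mean of the 4 areas, 969 transcripts were higher and 534 lower by limma, and 727 and 744 by edgeR. These tests treat libraries of 1 set as independent although they deviated together, so their p-values are too small. With a random effect of the root-tip set 343 transcripts were called. With 1 mean per root-tip set, 24 were called, 18 higher and 6 lower. On reads summed per set edgeR called 0, with 3911 at an unadjusted p below 0.05. By set means, pp_103534 and pp_103535 rose by 3.91 and 3.46 on the log2 scale (adjusted p = 0.00238 for both, limma), and pp_64764 and pp_93274 fell by 2.97 and 3.34 (adjusted p = 0.026 for both).

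The nitrate effect itself differed between areas for 50 transcripts by the limma F test. Of the 26 with the largest effect in the cap, 22 rose there, and of the 19 with the largest effect in the vascular tissue, 18 rose. These include runs of adjacent IDs with near-equal effects, which may be copies, so they are not counts of independent genes. The transcript pp_58111 rose from 8.75 ± 3.27 to 38.6 ± 8.52 CPM in the vascular tissue (SD, n = 3 each), and the F test gave an adjusted p of 0.0163 by limma and 1 by edgeR. Its group means in the cap and the meristem were under 0.1 CPM with either solution, so a change by the same factor could hardly show there on this scale. The fall of pp_86567 in the vascular tissue likewise had no counterpart that could show in the cap or the meristem, where it had 0 reads with KCl. The count was 6 by edgeR, 91 with the root-tip set as a block and 166 without KCl replicate 3 of the cap.

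**Figure D3:**
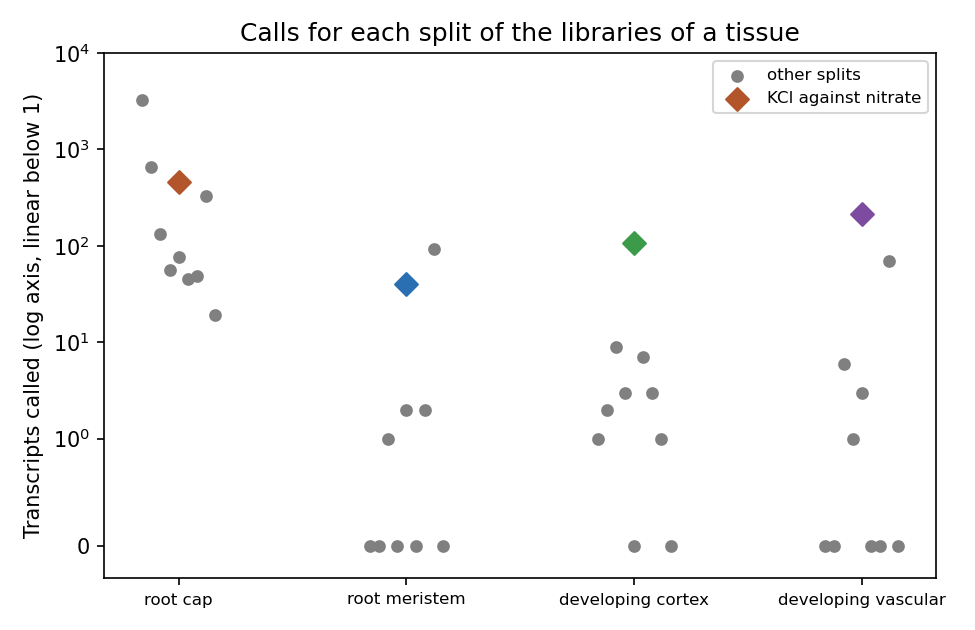
Number of transcripts called by limma (y axis, logarithmic above 1) for each area (x axis), with diamonds for KCl against nitrate and grey points for the other 9 splits of the 6 libraries into 3 and 3. The real split had 463, 40, 106 and 212 calls in the cap, meristem, cortex and vascular tissue, and the highest other split had 3227, 93, 9 and 69.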

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

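The F test of the difference between areas was planned, and the splits behind it and the free relabellings of the area comparison were set before their results were seen. The relabellings within sets and the shares of cap transcripts in other splits were added later, after related results had been seen, and the other tests in this part were chosen after the results they bear on. Groups of 3 libraries are too small for a test of single outlying libraries.

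A difference between areas marked the nitrate effect of 50 transcripts by the limma F test, and 4 named transcripts were among them. Their adjusted p-values for that difference were 0.00657 for pp_64764, 0.00657 for pp_86567, 0.0454 for pp_93557 and 0.0163 for pp_58111. By edgeR they were 1, 0.854, 1 and 1, and 6 transcripts differed in all. On the log2(CPM + 0.5) scale these differences follow the level of a transcript in each area. With nitrate pp_64764 had 0 reads in every area, and its KCl level was 0.52 to 11.4 CPM, while pp_93557 had 0.326 CPM with KCl in the cap and pp_86567 had 0 reads there. Group means of pp_58111 in the cap and the meristem were under 0.1 CPM. The values therefore do not show that nitrate acted on these transcripts in some areas and not in others. In 3 of the 10 splits of the 6 root-tip sets into 3 and 3, the real one included, the count was at least the 50 of the real split. The highest other split had 69. With 10 splits, no share below 0.05 can be reached.

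The same limit holds for the other nitrate counts, since 3 libraries or sets against 3 make 10 splits. The numbers of splits given next include the real one. In the cap, 3 splits gave as many calls as the real 463, and the highest other split, KCl 1, KCl 2 and nitrate 1 against the rest, gave 3227, several times the real count. Such a split points to a structure of the cap libraries that does not follow the solution. In the meristem 2 splits reached the real count of 40 and the highest other had 93. For the mean of the 4 areas 2 splits reached 1503 and the highest other had 2197. In the cortex and the vascular tissue the real split alone (1 of 10) reached 106 and 212 calls, and the highest other had 9 and 69. For the area comparison, 100 relabellings of the 24 libraries, the real one included, gave as many calls 1 time for the cap, 2 for the meristem, 3 for the cortex and 1 for the vascular tissue. The real counts were 40490, 31803, 21903 and 31495, and the highest others 21379, 33094, 29444 and 22170. These relabellings ignore that libraries of a set deviate together. When the areas were relabelled only within each of the 6 sets, 1, 1, 3 and 1 of 100 gave as many calls, and the highest others were 18668, 23985, 33105 and 22069. The share of relabellings with as many calls was below 0.05 for each area in both, from 100 draws and without adjustment over the areas. In the cortex, 2 other relabellings reached the real count in each way, and in the meristem 1 did in the free one. Counts as large thus also arose without the true areas. The counts alone do not exclude chance for the cortex, or for the meristem in the free relabelling.

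Transcripts such as pp_64764 are a pattern to look at again: they had at least 1 CPM in at least 2 areas of each set of 1 solution and under 0.1 CPM in every library of the other. There were 12 of them, 9 present with KCl and 3 with nitrate. They include adjacent IDs that may be copies, such as pp_64760 and pp_64761 or pp_93556 and pp_93557. The counts of splits below are therefore counts of IDs and not of independent genes. Not all lacked reads on the low side, where pp_93557 had 12 reads over 12 libraries. Too few reads argue poorly for it, since a median of 202 reads per library was to be expected on the low side. Differences between the root-tip sets remain open, for instance in seedling genotype: another split of the sets (KCl 1, nitrate 1 and nitrate 3 against the rest) held 13 such transcripts, and single sets held 5 to 31 that met these limits in that set alone. Switching by nitrate cannot be told apart from it, since the real count of 12 lies below the highest other split and above the median other split of 5.

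The surplus of transcripts with their highest mean in the cap among the cap rises may come in part from the spread pooled over the 4 areas. Such a spread would favour these transcripts in any split of the cap libraries. In the other 9 splits they made up a median of 64.4% of all calls (19.5% to 100%). Their share was 72.1% in the real split and 39.1% among all tested transcripts. A pooled spread would favour rises and falls alike, but in the real split they made up 84.7% of the rises and 31.2% of the falls. Other splits were one-sided too, such as KCl 1, KCl 2 and nitrate 1 against the rest (83.6% and 2.78%). For KCl 1, nitrate 1 and nitrate 2 against the rest both shares were 85.7%. A pooled spread alone therefore does not account for the one-sided shares. Unequal shares of cap tissue between libraries would raise these values too, so the splits do not separate how much each explanation gives. A higher share of cap tissue in the nitrate cap libraries stays open. The cap-highest share of CPM was 61% ± 6.91 with KCl and 64.4% ± 0.749 with nitrate (SD, n = 3 each, two-sided exact permutation p = 0.4, where 0.1 is the smallest possible), a difference of 3.41 points. The KCl libraries ran from 55.3% and 58.9% to 68.7% in replicate 3, the nitrate libraries from 63.7% to 65.2%, so the lack of a clear difference rests on KCl replicate 3, without which the cap calls rose from 463 to 2626. Earlier criteria used 1684 cap transcripts near the floor elsewhere and were dropped after their results had been seen. For these, a ratio of 1.79 of the residual SD in the cap to the pooled SD is at least partly set by their selection. The median residual SD of all tested transcripts was also largest in the cap (0.371, against 0.252 to 0.274 in the other areas and 0.331 pooled). The median change of the 1684 transcripts, 0.508 on the log2 scale, was first set against the median called rise of 1.56. This would have counted against more cap tissue but compares with rises selected for size. It was then set against their median absolute deviation of 0.633, which measures single transcripts. A response of cap transcripts to nitrate also stays open, although 12 of the 38 edgeR rises in the cap had their highest mean there.

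The KCl replicate 1 libraries lay apart from the other KCl libraries in every area on principal component 4, which held 3.86% of the variance. RNA exchanged between the cap and its neighbours would make their deviations run in opposite directions over cap-highest transcripts. With the cap, the deviations correlated at 0.424 (meristem), 0.588 (cortex) and 0.25 (vascular tissue) over these transcripts. Over all transcripts they correlated at 0.543, 0.616 and 0.414. Since the libraries of this set deviated together over all transcripts, a positive value cannot count against exchange, which stays open. Deviations correlated by at least 0.414 between the areas of that set. This restates that its libraries deviated alike and is no separate evidence of something shared. It does not single out the set, since the 36 pairs over all sets had 0.279 to 0.694. Shared plants, a shared day and a shared processing batch stay open, since the labels give none of them, and no biological explanation was tested.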

How the results depend on the processing

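The tests listed last in the methods (voom, DESeq2, the random effect, set means, summed reads, edgeR with a block, the area filter and whole sets left out) were chosen after seeing the data. Of 1310 values of named transcripts under alternatives, in the contrasts that name them and without the F test of the difference between areas, 1289 kept direction and call, 21 lost the call and 0 reversed. Of the 21, 10 were lost in fits on the libraries of an area alone, 4 with the area filter, 4 with edgeR on summed reads and 3 with voom. The 4 lost with summed reads were all the values named for the mean nitrate effect. Named transcripts were chosen for their small p-values in these same libraries, which the alternatives reuse. The high share of kept calls is therefore largely built in and is no separate support. The F test called 4 named transcripts by limma, and edgeR called none of these 4 (adjusted p of 0.854 to 1). The area comparisons of the cap (27529 to 42746) and the vascular tissue (22352 to 34765) stayed within 1.5 times of the main count under all alternatives. The majority of higher or lower calls in the area comparisons turned under several alternatives. In the cap, higher calls led with median-of-ratios scaling (20996 to 19408), edgeR (20465 to 19478), voom (20060 to 18979), DESeq2 (21494 to 19159) and the filter at 5 CPM (14026 to 13503). Lower calls led with the filter at 5 CPM in the meristem (11122 to 10618) and the vascular tissue (11385 to 10967), with KCl alone in the vascular tissue (12448 to 11869), and with median-of-ratios scaling in the meristem (16521 to 14887). The cause of the moves below was not tested unless named.

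The counts of nitrate calls are given for the cap, meristem, cortex and vascular tissue in turn, where they moved by over 1.5 times. A pseudocount of 0.1 gave 217 in the cap and 130 in the vascular tissue, and 2 gave 808 and 418. A filter at 5 CPM, which tests fewer transcripts, gave 148, 22, 64 and 106. Library weights gave 139 in the meristem, 187 in the cortex and 514 in the vascular tissue. The libraries of an area alone gave 0, 0, 33 and 8, with fewer libraries for the spread, and 6, 1, 34 and 23 with the area filter. Counts were 118, 17, 51 and 78 by edgeR, 288, 9, 42 and 102 by voom, and 1126, 155, 249 and 340 by DESeq2. Of the DESeq2 calls in the cap, 341 were higher and 785 lower.

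For the mean of the 4 areas, the filter at 5 CPM gave 832, library weights 4093, voom 717, DESeq2 3605, the random effect 343, set means 24 and summed reads 0. For the difference between areas, the pseudocounts gave 18 and 158, the filter at 5 CPM 18, library weights 110, no variance trend 114, edgeR 6, edgeR with a block 3, voom 3, the random effect 143 and the replicate block within solution 91. KCl libraries alone, with fewer libraries, gave 16700 calls in the meristem and 7158 in the cortex, and 277, 591 and 1414 transcripts highest in the meristem, cortex and vascular tissue. The filter at 5 CPM gave 851 and 1469 highest in the meristem and vascular tissue. Library weights gave 2464 and the replicate block within solution 2047 highest in the meristem.

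Whether the experiment numbers pair the solutions stays open. Deviations of same-numbered libraries of an area correlated between solutions at -0.0429 to 0.298 (median 0.0999, 12 pairs), and those with other numbers at -0.303 to 0.175 (median -0.0373, 24 pairs). All 4 pairs of number 1 were above 0.1. The replicate block on the number gave 67 calls in the meristem and 3124 for the mean, and changed no other count by over 1.5 times.

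Leaving out a library or a whole set gave 208 to 2626 calls in the cap, 28 to 119 in the meristem, 76 to 198 in the cortex and 106 to 483 in the vascular tissue. The range was 685 to 3469 for the mean, 12 to 166 for the difference between areas and 730 to 1599 transcripts highest in the meristem. Without the cap library of KCl replicate 3 the cap had 2626 calls, the mean 3469 and the difference 166, and without the whole set the counts were 2144 in the cap, 73 in the meristem, 198 in the cortex, 483 in the vascular tissue, 3150 for the mean and 876 highest in the meristem. Without the vascular library of KCl 3 that area had 405. Without the set KCl 1 the meristem had 119 and the cortex 193 calls, and without the KCl 1 vascular library that area had 140. Without the set KCl 2 the cap had 276. Without the nitrate 1 set the cap had 256 and the mean 685. Without nitrate replicate 2, the cap had 785 (cap library), the meristem 99 (set) and the vascular tissue 106 (vascular library). Without the nitrate 3 set the cap had 208, the mean 769 and the meristem 730 highest. The 50 differences between areas fell to between 12 and 31 without any of 14 libraries or sets, and rose to 104 without the cap library of nitrate 2, 80 without the vascular library of KCl 3 and 106 without the set KCl 3. With at least 45262154 reads per library, 3 reads correspond to at most 0.074 CPM. At this depth and with 3 libraries per group, 16% to 22% of simulated changes of 1 on the log2 scale were recovered. These changes were set in transcripts with a KCl mean of at least 1 CPM in the area. The gene-list results and their alternatives were not run, since no ID had a gene name.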

Other observations

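The tests in this part were chosen after the data had been seen. The nitrate effects correlated between areas at a median Pearson's r of 0.5 across transcripts, which are not independent replicates, and the other 9 splits of the root-tip sets gave 0.393 to 0.573. The median covariance of the effects was 0.098 in the real split and 0.0717 to 0.0917 in the others. Most of the likeness between areas is therefore also present in splits that mix the solutions.

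Among transcripts highest in the vascular tissue, the median nitrate change in that tissue was 0.375 on the log2 scale over 2509 transcripts. In the cap, cortex and meristem the 14566, 1622 and 1325 transcripts highest there had medians of 0.0843, 0.0958 and -0.0389. The same 2509 transcripts had medians of 0.21 in the cortex, 0.0941 in the meristem and 0.0154 in the cap. In the vascular tissue, transcripts highest in the cap, the cortex and the meristem had medians of 0.165, 0.163 and -0.178. Transcripts were placed by area means over both solutions of these libraries, so a rise in an area favours its own class. The medians were not tested between libraries. In vascular libraries the 2509 transcripts held 5.675% ± 0.939 of the CPM with KCl and 6.574% ± 0.725 with nitrate (SD, n = 3 each). Single libraries overlapped, with up to 6.484% with KCl and from 5.828% with nitrate.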
